A study of Mus musculus with 6 samples.

How the data were processed

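Total RNA of 6 samples of mouse satellite cells, 3 labelled Magic-F1 and 3 labelled control, was labelled with Cy3 and hybridised to 6 Agilent single-colour arrays of design 014868 with 45018 spots each, per the labels and the file headers. Viral polyadenylated transcripts were spiked into each RNA, per the labels' protocols. Per the file headers, Agilent Feature Extraction 10.5.1.1 gave each spot's intensity as a background-subtracted processed signal, together with the raw spot mean, the local background median and flags, without normalization between arrays. The authors also deposited 1 table with a log2 value per spot and array. For 4 arrays this table equals the log2 of the processed signal to within 5e-09, with no centring. For both arrays numbered 1 it holds other values on the same scale (SD of the difference 0.456 for Magic-F1 and 0.472 for control, with 0% of 43379 non-control spots equal within 1e-06). The medians of its log2 columns were 3.53, 3.50 and 3.59 for Magic-F1 replicates 1, 2 and 3, and 3.32, 3.35 and 3.40 for control replicates 1, 2 and 3. What else was done to the columns numbered 1 is not given in the sources used here.

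The analysis started from the scanner files. Groups were taken from the sample labels. Control spots were left out, spots flagged as outliers (59 to 89 per array) were set to missing, and log2 processed signals were reduced by each array's 75th percentile over non-control spots. Spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group. Of 41174 non-control probes, 25097 were named by matching their RefSeq accession to a gene table of mouse assembly GRCm38.p6, used for names only, and 16077 kept the name in the files. Probe positions are those of the files, on mm9. A named gene was represented by its tested probe with the highest mean over the 6 arrays. Of 4737 genes with several tested probes, 637 called genes had another probe called in the opposite direction.

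Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all tested probes at 0.05, 2-sided. The median residual SD was 0.090 on the log2 scale. Fold changes are powers of 2 of the fitted log2 change. Where a group was not well above background on any of its arrays, the change is given as at least N-fold. This bound is the other group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, on the normalized log2 scale. Bounds and folds of dim genes depend on the background correction. Other probes of a named gene are given where they were not called, went the opposite way or differed by over 1 on the log2 scale. The report gives the log2 change with normexp background for its genes stated as a bound and for those whose fold was over 1.5 times smaller with it. Gene lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 28 lists with at least 5 tested members, and again with an estimated correlation and with fry. The list of sex check genes was not tested as a list. The tests were tried on simulated arrays built from the means and spreads of 21186 probes, with 200 probes changed. They recovered 60% of changes of log2 0.5, 82% of log2 1, 94% of log2 2 and 78% of log2 −1, with 7 false calls among 20986 unchanged probes. A list shifted by log2 0.5 was found and 0 other lists were called. The simulated values were already normalized, their noise was independent between probes, and few probes changed. The simulation therefore does not show how often lists of correlated genes are falsely called. Nor does it show errors of scaling where most probes change.

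The genes named in the report were set by a rule fixed before the data were examined. Other genes, in the part on other observations, were chosen after their values were seen. The rule takes Met, Hgf, Vegfa, Akt1, Pax7, Myod1 and Myog, the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap, leaving out names of clones or predicted loci, and up to 4 members of each list, called ones first and then by size of change.

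Replicates were compared over 126 bright probes that are spotted 10 times per array. Arrays of a group differed by 0.039 to 0.165 log2 (SD) beyond the noise between spots. Control replicates 1 and 2 were the closest (0.039), and control replicate 3 differed from them by 0.147 and 0.165. The Magic-F1 arrays differed by 0.067 to 0.076. Repeat arrays of 1 RNA could differ as much, so this does not show that the samples are separate, and they were counted as the labels give them. Replicates 1 and 3 of both groups lay on slide 1 and replicate 2 of both groups on slide 2, so slide was tried as a block and results were computed within slides. Other alternatives covered background correction, normalization, filters on dim probes, variance models, array weights, the authors' table, leaving out each array and averaging the probes of a gene. Scaling to 8 spiked-in probes, no scaling, leaving out both arrays numbered 1, averaging control replicates 1 and 2, and a 4-fold threshold were added after seeing the data. Expression of the transgene was not analysed here, since no probe is annotated for it.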

Results

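RNA was measured in mouse skeletal muscle satellite cells, the resident stem cells of muscle fibres, taken in proliferation. One group came from mice homozygous for Magic-F1, an engineered ligand derived from hepatocyte growth factor (HGF) that activates the receptor MET, and the other from control mice. The series gives the genotype of the former as +/+, while the control sample titles carry the word MLC3F, whose meaning the labels do not give. Each group held 3 samples, and each sample was hybridised to 1 single-colour Agilent array. The series describes its mice as a model of skeletal muscle hypertrophy, and the comparison asks which transcripts differ between Magic-F1 and control satellite cells. No probe was annotated as the Magic-F1 transgene, so the mouse Hgf and Met probes do not check the group labels. The 75th percentile of the spot signal was 348 ± 7.78 on the Magic-F1 arrays and 282 ± 8.93 on the control arrays (SD, n = 3 each). Between 49.2% and 52.0% of the non-control spots of an array were well above background, and 0 were saturated. With 3 arrays per group, the number of arrays limits the precision. The labels call the samples biological triplicates without naming separate animals or cultures. The source names of all samples end alike in rep1, and the replicate numbers come from the sample titles. P-values therefore measure only the spread between these samples, which may be technical.

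The arrays of a group resembled each other far more than those of the other group. Over the tested probes the mean Pearson correlation was 0.997 within groups and 0.847 between groups. The lowest correlation within a group was 0.996 and the highest between groups was 0.848. The difference of 0.15 was the largest of the 10 possible splits of the 6 arrays, which gives a one-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow.

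Muscle regulators were lower on the Magic-F1 arrays and macrophage genes were higher. RNA of whole samples cannot tell a different mixture of cells from changes of expression within satellite cells. This limit holds for all results below. Myogenin (Myog), which drives myoblasts into differentiation, was 25.02-fold lower (log2 −4.64, SE 0.05), and Myod1, the myoblast determination factor, was 18.5-fold lower (log2 −4.21, SE 0.07). Pax7, the transcription factor that marks satellite cells, was at least 4.63-fold lower, since it was not well above background on any Magic-F1 array. Met, the HGF receptor, was 6.25-fold lower (log2 −2.64, SE 0.06), while Hgf was 1.47-fold higher (log2 0.56, SE 0.08). The largest rise was that of Cd5l, a protein secreted by macrophages, which was at least 2371-fold higher. S100a9, a calcium-binding protein abundant in neutrophils, showed the largest fall and was at least 18830-fold lower. All of these changes passed limma's test with Benjamini-Hochberg adjustment, with adjusted p between 2.03e-08 for Cd5l and S100a9 and 0.000731 for Hgf. Folds of dim genes depend on the background correction. With normexp background and an offset of 50, all 29 genes given as at least N-fold and the other 114 genes named by rule kept their direction and call. The former all changed by less than the bound, and 51 of the latter had folds over 1.5 times smaller. Log2 changes with normexp are given below for such genes. With normexp background the log2 changes were −0.77 (Pax7), −1.69 (Met), 8.41 (Cd5l) and −11.46 (S100a9).

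In signal relative to each array's 75th percentile, Myog stood at log2 3.24 ± 0.02 in Magic-F1 and 7.88 ± 0.05 in control cells (SD, n = 3 each). Myod1 stood at 0.35 ± 0.03 against 4.57 ± 0.11, Met at −3.01 ± 0.05 against −0.37 ± 0.09, and Hgf at −0.21 ± 0.06 against −0.77 ± 0.14. The probes of these genes lie, in mm9 coordinates of the files, on chromosome 1 at 136188874 to 136188933 (Myog), chromosome 7 at 53633956 to 53634015 (Myod1), chromosome 6 at 17523765 to 17523824 (Met) and chromosome 5 at 16124829 to 16124888 (Hgf). A second Met probe was also lower (log2 −1.45) and a second Hgf probe also higher (log2 0.69). Vegfa, the main endothelial growth factor, was 1.52-fold lower (log2 −0.61, SE 0.05), and its other 3 tested probes fell by 0.79 to 1.19 on the log2 scale. Scaling to the spiked-in transcripts left Vegfa at log2 −0.15 with an adjusted p of 0.0524, and over the 22 alternatives its adjusted p ranged from 6.38e-07 to 0.0524. Akt1, a kinase downstream of MET, was 1.24-fold higher (log2 0.31, SE 0.06), with a second probe at 0.29. The size of the Akt1 change depended on the scaling, with log2 0.57 under quantile normalization and 0.44 with the median of each array.

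**Figure D1:**
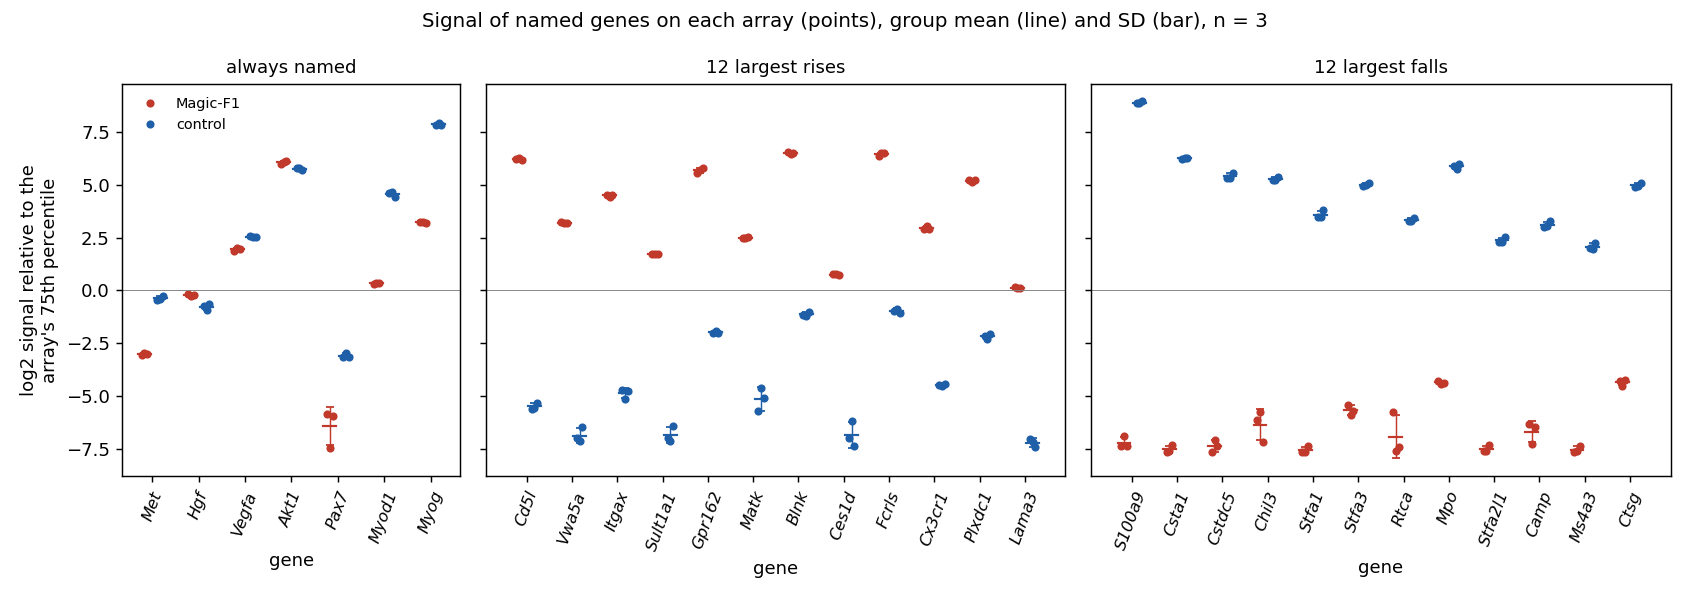
Signal of the genes named by rule on each of the 6 arrays, in log2 relative to the array's 75th percentile (y axis), by gene (x axis). Points are arrays, horizontal lines group means and bars SDs (n = 3). Myog lies near 3.24 in Magic-F1 and 7.88 in control cells. The 12 largest rises and 12 largest falls were chosen among genes whose groups do not overlap.

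Several of the 12 genes with the largest rises are known from macrophages and related cells. Itgax, the integrin CD11c, was 662-fold higher and was well above background on 1 of 3 control arrays. Fcrls, an Fc receptor-like protein of macrophages and microglia, was 173-fold higher, and Cx3cr1, the fractalkine receptor, 172-fold higher. Blnk, an adaptor of immune receptor signalling, rose 201-fold and the kinase Matk 201-fold, the latter being well above background on 1 of 3 control arrays. Gpr162, an orphan receptor, rose 204-fold and Plxdc1, a membrane protein with a plexin domain, 166-fold. The remaining 4 were not well above background on any control array. Vwa5a was at least 291-fold higher, the sulfotransferase Sult1a1 at least 104-fold, the carboxylesterase Ces1d at least 53.2-fold and laminin alpha 3 (Lama3) at least 34.5-fold. Second probes of Itgax, Matk, Cx3cr1 and Lama3 rose less, by log2 3.74, 1.55, 4.43 and 2.65, and that of Fcrls rose more, by 11.31. Under normexp the log2 changes were 6.46 (Itgax), 5.06 (Cx3cr1), 4.62 (Matk), 6.82 (Gpr162), 6.44 (Plxdc1), 5.51 (Vwa5a), 4.06 (Sult1a1), 3.11 (Ces1d) and 2.69 (Lama3).

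Genes of neutrophils and their precursors made up most of the 12 largest falls. Myeloperoxidase (Mpo) was 1208-fold lower and cathepsin G (Ctsg) 644-fold lower, and both were well above background on all 6 arrays. The others were not well above background on any Magic-F1 array. Among them the antimicrobial peptide gene Camp was at least 344-fold lower, the chitinase-like Chil3 at least 1547-fold, and Ms4a3, a gene of granulocyte precursors, at least 166-fold. The falls included 5 genes of the stefin A family of protease inhibitors. Csta1 was at least 3023-fold lower, Cstdc5 at least 1690-fold, Stfa3 at least 1281-fold, Stfa1 at least 476-fold and Stfa2l1 at least 204-fold. Rtca, an RNA cyclase, was at least 402-fold lower by its brightest probe, whereas its second probe was higher (log2 2.53), so the direction for Rtca depends on the probe. Normexp background gave log2 changes of −7.96 (Mpo), −7.14 (Ctsg), −5.61 (Camp), −7.77 (Chil3), −4.69 (Ms4a3), −8.84 (Csta1), −7.97 (Cstdc5), −7.31 (Stfa3), −6.19 (Stfa1), −5.00 (Stfa2l1) and −5.88 (Rtca).

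Most of the measured transcriptome differed between the groups. Of 12838 genes tested with limma, 11456 passed an adjusted p of 0.05, 5241 of them higher and 6215 lower in Magic-F1 cells. Changes of at least 2-fold were seen for 3061 genes that rose and 3681 that fell, and changes of at least 10-fold for 560 and 572 genes. The 3 values of each group did not overlap for 11650 genes (90.7%), against 10% by chance. Over probes, 18590 of 21190 passed, 8749 higher and 9841 lower. Scaling to the spiked-in transcripts moved the median change of all tested genes from log2 −0.16 to 0.30 and the split over probes to 11122 higher and 7214 lower, so small changes in either direction depend on the scaling. Fitted with slide as a block, 18617 probes and 11462 genes passed. Within slide 1, which held 2 arrays of each group, 17675 probes passed. Of 10890 genes called on slide 1 alone, 10855 (99.68%) changed in the same direction on slide 2, which held 1 array of each group.

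Gene groups were compared through 29 lists fixed before the data were examined, of which 28 were tested with camera at a preset correlation between genes of 0.01. The test called 11 lists, 4 shifted up and 7 down. With an estimated correlation 0 of the 11 calls held. The estimate for the endothelial list was 0.016, close to the preset 0.01, yet its adjusted p in camera rose from 0.0204 to 0.328. The lost calls therefore cannot be read as an effect of correlation between genes alone. Members were counted by the limma test over all tested probes, and adjusted over the list alone the counts differed in 1 list, immediate early and stress genes (22 higher and 9 lower, against 22 and 8). With slide as a block camera also called 4 lists up and 7 down. Medians of 7 lists without a call changed sign in at least 1 alternative of the processing. For uncalled lists the range of the median over all alternatives is given after it.

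**Figure D2:**
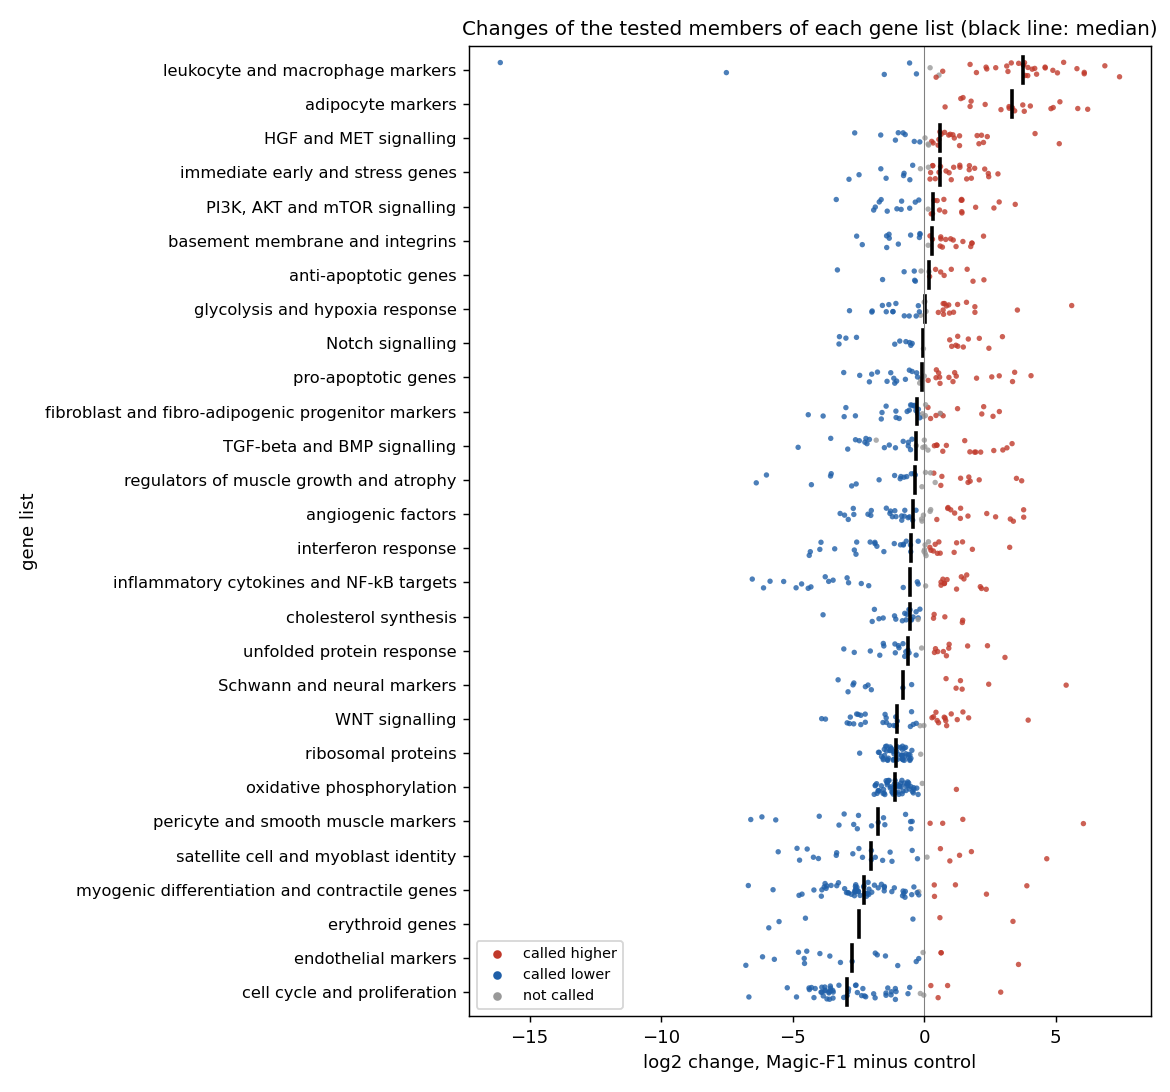
Log2 change (Magic-F1 minus control, x axis) of the tested members of the 28 gene lists (y axis). Points are genes, red where called higher, blue where called lower and grey where not called, and black lines are list medians, from −2.93 for cell cycle genes to 3.76 for leukocyte and macrophage markers.

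The muscle programme was lower across its differentiation and identity genes. Of 64 tested myogenic differentiation and contractile genes, 58 fell and 5 rose, with a median log2 change of −2.30 (−2.27 and −2.35 within slides 1 and 2). Cardiac actin (Actc1), the form made in developing muscle, was 103-fold lower (log2 −6.69, SE 0.05), muscle creatine kinase (Ckm) 53.7-fold lower and caveolin 3 (Cav3) 27.1-fold lower. Camera gave this list an adjusted p of 2.4e-08, and an adjusted p of 0.328 with an estimated correlation. Among 25 satellite cell and myoblast identity genes, 19 fell and 5 rose, with a median of −2.01 (−1.97 and −2.10 within slides). The growth factor receptor Fgfr4 was 46.9-fold lower, M-cadherin (Cdh15) 28.5-fold and Dlk1 26.7-fold, while the chemokine receptor Cxcr4 was 25.2-fold higher. The other 2 Fgfr4 probes fell by 3.01 and 4.71 on the log2 scale, and a second Cxcr4 probe rose by 3.59. This list had an adjusted p of 0.0307 at the preset correlation and 0.574 with an estimated correlation. The median was −1.16 with normexp background. Restricted to probes well above background on all 6 arrays, the identity list had a median of −1.58 and an adjusted p of 0.0999 (0.00344 to 0.0999 over the 22 alternatives). These falls went together with higher macrophage and adipocyte markers (list medians 3.76 and 3.35). With normexp background the log2 changes were −4.97 (Ckm), −4.76 (Fgfr4), −4.04 (Dlk1) and 4.03 (Cxcr4).

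Of 30 regulators of muscle growth and atrophy, 16 fell and 10 rose, with a median log2 change of −0.36 (range −0.44 to 0.10) that became 0.10 under spike-in scaling, and the list was not called (adjusted p = 0.616). The stretch-responsive Ankrd2 was 83.5-fold lower and the muscle LIM protein Csrp3 19.5-fold lower. Myostatin (Mstn), which restrains muscle growth, was at least 13.7-fold lower, and the activin subunit Inhbb was 13.02-fold higher. Under normexp the log2 changes were −1.69 (Mstn) and 2.75 (Inhbb).

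Cell cycle genes were lower in the Magic-F1 cells. Of 55 tested genes 49 fell and 4 rose, with a median log2 change of −2.93 (−2.996 and −2.85 within slides, and −1.99 with normexp background). Rrm2, which supplies deoxynucleotides for DNA synthesis, was 101-fold lower (log2 −6.66, SE 0.06). Cyclin B1 (Ccnb1), the mitotic cyclin, was 36.9-fold lower, cyclin E2 (Ccne2) 28.9-fold and thymidylate synthase (Tyms) 20.8-fold. A second Ccne2 probe fell by 3.83 on the log2 scale. For the cell cycle list the adjusted p was 3.78e-08, and 0.142 with an estimated correlation. Ribosomal protein genes fell for 51 of 52 members with 0 rising (median −1.07, and −1.05 and −1.11 within slides). The size of this shift depended on the scaling, with a median of −0.45 under quantile normalization and −0.61 under spike-in scaling. Falls included Rpl10a (log2 −2.46), Rpl24 (log2 −1.74), Rps6 (log2 −1.71) and Rpl18 (log2 −1.62). Oxidative phosphorylation genes fell for 58 of 60 and rose for 1 (median −1.11, and −1.11 and −1.05 within slides, −0.79 under quantile normalization and −0.65 under spike-in scaling), including the respiratory chain subunits Ndufs4 (log2 −1.90), Cyc1 (log2 −1.86), Ndufb6 (log2 −1.86) and Uqcrc2 (log2 −1.81). The adjusted p of these lists was 6.11e-08 and 2.79e-07, and 0.574 and 0.58 with an estimated correlation. The falls of all 3 lists went together with the rises of macrophage and adipocyte markers (list medians 3.76 and 3.35) and the falls of the neutrophil genes S100a8 and S100a9. Normexp background gave log2 changes of −4.46 (Rrm2) and −3.28 (Ccne2).

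Leukocyte and macrophage markers rose as a group while the neutrophil calgranulins within the list fell. Of 37 tested markers 30 were higher and 5 lower, with a median log2 change of 3.76 (3.73 and 3.80 within slides, and 3.31 with genes below background at their bound). C1qc, a complement component made by macrophages, was 116-fold higher (log2 6.86, SE 0.05), at 7.55 ± 0.05 against 0.69 ± 0.04 (SD, n = 3 each). S100a8, the partner of S100a9, was 184-fold lower. Camera gave an adjusted p of 3.18e-07, and 0.233 with an estimated correlation. In the control cells 33 of the 37 markers were well above background on all 3 arrays. The median was 3.13 with normexp background, and adipocyte markers rose with it (list median 3.35). With normexp background the log2 change was −5.58 (S100a8).

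Adipocyte markers were higher for 19 of 19 tested genes, with a median log2 change of 3.35 (3.33 and 3.40 within slides). The lipid droplet protein Cidec was 74.1-fold higher, carbonic anhydrase 3 (Car3) 57.1-fold (log2 5.83, SE 0.04), complement factor D (Cfd, adipsin) 35.6-fold, and resistin (Retn) at least 16.0-fold. Camera gave an adjusted p of 1.81e-07, and 0.142 with an estimated correlation. In the control cells 17 of the 19 genes were well above background on all 3 arrays. Adipocyte markers rose together with macrophage markers (list median 3.76). Under normexp the log2 changes were 5.25 (Cidec) and 1.71 (Retn).

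Most of the listed vessel genes were lower. Of 21 endothelial markers 17 fell and 3 rose, with a median log2 change of −2.74 (−2.71 and −2.80 within slides) that became −1.86 with genes below background at their bound. The tight junction protein Cldn5 was 110-fold lower and was well above background on 1 of 3 Magic-F1 arrays. Endomucin (Emcn) was 51.9-fold lower, Robo4 at least 18.7-fold and the transcription factor Sox18 at least 15.8-fold. The adjusted p was 0.0204, and 0.328 with an estimated correlation. The endothelial median was −0.97 with normexp background. Over probes well above background on all 6 arrays, which leaves out genes lost from the Magic-F1 signal, the median was −0.30 with an adjusted p of 0.55 (0.00381 to 0.55 over the 22 alternatives). Of 21 pericyte and smooth muscle markers 17 fell and 4 rose, with a median of −1.75 (−1.74 and −1.75 within slides). Rgs5, a pericyte marker, was at least 25.5-fold lower, the potassium channel Kcnj8 72.0-fold lower and Higd1b at least 14.7-fold lower, while the aminopeptidase Anpep was 66.2-fold higher. A second Kcnj8 probe fell by 3.63 on the log2 scale. Vessel genes fell together with the rises of macrophage and adipocyte markers. For this list camera gave 0.0191, and 0.574 with an estimated correlation. Normexp background gave log2 changes of −3.67 (Cldn5), −4.24 (Emcn), −1.80 (Robo4), −1.70 (Sox18), −2.25 (Rgs5), −4.01 (Kcnj8) and −1.48 (Higd1b).

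The list of angiogenic factors went both ways. Of 41 tested genes 22 fell and 14 rose, and camera did not call it (adjusted p = 0.752). Its median was −0.44 (range −0.56 to 0.02), and 0.02 under spike-in scaling. Pdgfb, which recruits pericytes, was 13.7-fold higher (log2 3.78, SE 0.11), the hypoxia factor Epas1 13.7-fold, neuropilin 1 (Nrp1) 10.4-fold and S1pr1 9.65-fold. A second Nrp1 probe was higher by log2 1.63. With normexp background the log2 change was 2.37 (Pdgfb).

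Genes around HGF and MET were mostly higher although Met itself was lower. Of 31 tested genes 20 rose and 8 fell, with a median log2 change of 0.59 (0.59 and 0.60 within slides). Mst1, an HGF-like ligand of another receptor, was 35.0-fold higher and was well above background on 1 of 3 control arrays. The proteases St14 and Hpn, both able to activate HGF, were 18.5-fold and 5.26-fold higher. The list had an adjusted p of 0.0307, and 0.574 with an estimated correlation. Over probes well above background on all 6 arrays the median was 0.56 and the adjusted p 0.0812, the highest of the 22 alternatives, which began at 0.00627. The median ranged from 0.32 with normexp background to 1.05 under spike-in scaling. This rise went together with the larger ones of macrophage and adipocyte markers (list medians 3.76 and 3.35). Of 29 PI3K, AKT and mTOR genes 16 rose and 12 fell, with a median of 0.32 (range 0.25 to 0.77) and no call (adjusted p = 0.503). Igf1 was 6.27-fold higher and Igf2 10.1-fold lower. The catalytic subunit Pik3cb was 7.20-fold higher and Pik3cd 10.99-fold higher, the latter well above background on 2 of 3 control arrays. Under normexp the log2 changes were 2.50 (Mst1), 3.57 (St14), 1.18 (Hpn), −2.36 (Igf2), 1.08 (Pik3cb) and 1.21 (Pik3cd).

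Immediate early and stress genes rose for 22 of 32 members and fell for 8, with a median log2 change of 0.59 (0.59 and 0.60 within slides). Atf3 was 6.97-fold and Egr2 5.46-fold higher, while Gadd45g was 7.26-fold and Gadd45b 5.57-fold lower. The adjusted p was 0.0307, then 0.574 with an estimated correlation and 0.0582 under spike-in scaling, where the median was larger at 1.05 (0.00394 to 0.0582 over the 22 alternatives). Macrophage and adipocyte markers rose with this list (medians 3.76 and 3.35), and the neutrophil genes S100a8 and S100a9 fell.

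The apoptosis lists were not called. Of 16 anti-apoptotic genes 8 rose and 6 fell (median 0.19, range 0.14 to 0.65, adjusted p = 0.603), among them Cflar (4.82-fold higher), Bcl2l1 (3.61-fold higher), Mcl1 (3.10-fold higher) and Hspb1 (9.85-fold lower). Other probes rose less, 4 of Cflar by log2 0.29 to 1.59 and 1 of Mcl1 by 0.48. Of 34 pro-apoptotic genes 16 rose and 15 fell, with a median of −0.07 (range −0.16 to 0.39) and an adjusted p of 0.759. This median was above 0 under 4 of 5 other settings of scaling or background (0.39 with spike-in scaling). Caspase 1 (Casp1) was 10.2-fold higher, Casp9 at least 4.62-fold higher and Bok 8.34-fold lower. Bcl2l11 was 16.7-fold higher by its brightest probe and at log2 −0.01 by its second probe (adjusted p = 0.788). Normexp background gave a log2 change of 0.41 (Casp9).

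Inflammatory cytokines showed large falls within a list that was not called (13 of 32 higher, 18 lower, median −0.53, range −0.80 to 0.05, adjusted p = 0.603). Il6 was 69.0-fold lower (log2 −6.11, SE 0.07), the neutrophil-attracting chemokine Cxcl1 40.6-fold lower and Csf3, the granulocyte growth factor, at least 28.8-fold lower. Cxcl9 was 58.1-fold lower and well above background on 2 of 3 Magic-F1 arrays. Of 39 interferon response genes 21 fell and 12 rose (median −0.51, range −0.56 to −0.06, adjusted p = 0.372), with Cxcl10 20.7-fold, Isg15 15.7-fold and Iigp1 15.2-fold lower. Ifit1 was 20.1-fold lower and well above background on 2 of 3 Magic-F1 arrays. With normexp background the log2 changes were −5.16 (Il6), −3.85 (Cxcl1), −2.28 (Csf3), −3.24 (Cxcl9), −2.71 (Cxcl10), −3.27 (Iigp1) and −2.01 (Ifit1).

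Matrix and developmental signalling lists were not called either. Of 36 fibroblast and fibro-adipogenic progenitor markers 21 fell and 10 rose, with a median log2 change of −0.28 (range −0.35 to 0.17) that became 0.17 under spike-in scaling and 0.02 without scaling (adjusted p = 0.481). Ly6a, the stem cell antigen Sca-1, was 21.2-fold lower, Pi16 14.3-fold, Smoc2 7.88-fold and Gli1 at least 2.06-fold lower. Basement membrane and integrin genes rose for 15 of 27 and fell for 11 (median 0.31, range 0.18 to 0.77, adjusted p = 0.405), with fibronectin (Fn1) 3.52-fold and Itgb5 4.77-fold higher, and Itga3 5.93-fold and Itga1 5.12-fold lower. The other 2 Itga3 probes fell by 0.58 and 2.90 on the log2 scale. WNT genes fell for 26 of 42 and rose for 14 (median −1.04, range −1.06 to −0.52, adjusted p = 0.389). Sfrp2 was 13.5-fold and Fzd9 14.9-fold lower, and Dkk2 was 15.4-fold higher. Fzd3 was 7.62-fold lower and well above background on 2 of 3 Magic-F1 arrays, and its second probe fell by 4.41 on the log2 scale. TGF-beta and BMP genes fell for 17 of 37 and rose for 14, with a median of −0.30 (range −0.47 to 0.16) that became 0.16 under spike-in scaling and 0.002 without scaling, while camera leaned up (adjusted p = 0.928). Bmp4 was 27.7-fold lower, Bmp6 at least 10.55-fold lower and the BMP antagonist Grem1 10.1-fold higher. Bmp2 was 8.83-fold higher and well above background on 2 of 3 control arrays. Notch genes split into 10 higher and 10 lower of 21, with a test that leaned up (adjusted p = 0.694). Their median was −0.03 (range −0.24 to 0.47, 0.05 and −0.20 within slides). It was above 0 under 3 of 5 other settings of scaling or background. Heyl was 9.45-fold, Hes6 9.34-fold and the ligand Dll1 7.87-fold lower, and Lfng was 7.84-fold higher. Under normexp the log2 changes were −2.96 (Pi16), −0.56 (Gli1), −1.41 (Itga3), −1.26 (Itga1), −1.97 (Fzd9), 3.14 (Dkk2), −1.15 (Fzd3), −2.94 (Bmp4), −1.29 (Bmp6), 1.02 (Bmp2), −2.32 (Heyl), −2.03 (Dll1) and 1.86 (Lfng).

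Among metabolic and stress lists without a call, cholesterol synthesis genes fell for 19 of 25 and rose for 5 (median −0.54, range −0.58 to −0.08, adjusted p = 0.0948). Idi1 was 3.94-fold, Mvk 3.72-fold and Fdps 3.29-fold lower, while a second Fdps probe was not called (log2 0.15, adjusted p = 0.147). Glycolysis and hypoxia genes rose for 15 of 33 and fell for 14 (median 0.03, range 0.001 to 0.48, adjusted p = 0.603), from P4ha2 at 48.6-fold and Aldoc at 11.6-fold higher to Egln3 at 7.17-fold and Higd1a at 3.98-fold lower. A second Aldoc probe rose by log2 5.99. A second Higd1a probe was not called (log2 −0.12, adjusted p = 0.138). Genes of the unfolded protein response fell for 16 of 27 and rose for 10 (median −0.62, range −0.64 to −0.17, adjusted p = 0.545), with Asns 8.32-fold and Chac1 6.32-fold lower and Edem1 8.39-fold and Ero1b 5.29-fold higher. The other 2 Edem1 probes rose by log2 0.54 and 0.95. Schwann and neural markers fell for 9 of 15 and rose for 6 (median −0.81, range −0.86 to −0.36, adjusted p = 0.603), with myelin basic protein (Mbp) 42.0-fold higher and Tubb3 6.53-fold and Mal 7.44-fold lower, Mal being well above background on 1 of 3 Magic-F1 arrays. Of 6 erythroid genes 4 fell and 2 rose (median −2.47, range −2.50 to −0.25, and −1.62 with genes below background at their bound, adjusted p = 0.603), with the alpha globin Hba-a2 45.8-fold lower and Gata1 at least 7.06-fold lower. Hba-a1 was 60.0-fold lower and well above background on 2 of 3 Magic-F1 arrays, and Hbb-bh1 was at least 2.91-fold higher. Normexp background gave log2 changes of 4.70 (P4ha2), −0.98 (Mal), −3.71 (Hba-a2), −1.07 (Gata1), −3.46 (Hba-a1) and 0.27 (Hbb-bh1).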

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

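The numbers of called probes, genes and lists stayed within 1.5 times of the reported ones under alternatives of background, normalization, filter, variance model and samples. Spike-in scaling, no scaling, leaving out both arrays numbered 1, averaging control replicates 1 and 2 and the 4-fold threshold were chosen after seeing the data. Without 1 array at a time, 18014 to 18672 probes, 11137 to 11500 genes and 11 lists passed. Leaving out both arrays numbered 1 gave 17303 probes, slide 1 alone 17675 and the values the authors deposited 18543. A threshold of at least 2-fold gave 11077 probes and of at least 4-fold 4850, by construction. Camera with an estimated correlation called 0 lists and fry called 25, tests of different hypotheses. The similarity difference of 0.15 was 0.1234 with normexp background, 0.0531 without a filter on dim probes, 0.1407 with probes well above background on all 6 arrays, and 0.1495 to 0.1507 without 1 array at a time. The causes were not tested.

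Of the results of named genes, 3103 kept direction and side of the threshold, 3 lost their call and 1 reversed. Of 615 list results, 611 kept their side of the threshold and 4 lost their call, and no called list changed direction in the camera test, which is relative to other genes. The list median changed sign in 20, from 7 lists of which 0 were called. Rtca was at log2 2.53 (2.531) with probes well above background on all 6 arrays, since that filter removes its brightest probe and leaves the other. That filter also ended the calls of the HGF and MET, endothelial and satellite cell lists. Spike-in scaling ended those of Vegfa, Kdm5d, Ddx3y and immediate early genes and called 11122 probes higher and 7214 lower. It reversed 485 probe calls, against 73 without scaling, 47 with normexp and 44 with quantile normalization. Deviations from group means correlated little between Magic-F1 and control arrays of the same replicate number (−0.003, 0.108 and 0.069). Between arrays of different numbers the correlations were −0.115 to 0.048. The values for numbers 2 and 3 were thus the highest, so pairing by number is neither shown nor excluded. With the replicate number as a block 18543 probes passed. Between 49.2% and 52.0% of spots were well above background on an array, so genes below that signal in both groups are not covered.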

Other observations

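Genes of other blood cells changed strongly between the groups. The gene lists of this paragraph and all tests of explanations in this part were chosen after the results were seen. Of 21 tested neutrophil granule genes 19 were lower in the Magic-F1 cells and 1 was higher, with a median log2 change of −8.32 (−6.94 with genes below background at their bound). All 19 falls were smaller with normexp background. Pglyrp1, the gene at the median, was at −3.51 with it. Lactotransferrin (Ltf), a granule protein, was at least 294-fold lower and Prtn3, a granule protease, 14.8-fold lower, while the growth factor receptor Csf3r was 10.97-fold higher. Of 14 platelet and megakaryocyte genes 13 were lower and 1 higher, with a median of −3.89 (−3.39 at the bounds). Pf4, a platelet chemokine, was 10.96-fold lower, and Ppbp 136-fold lower and well above background on 1 of 3 Magic-F1 arrays. Vwf, the 1 member that rose (log2 3.58), is also in the endothelial list, as is Selp. Of 25 tissue macrophage genes 24 were higher and Axl was lower (log2 −1.03), with a median of 3.90. Trem2, a macrophage lipid receptor, was 88.7-fold higher, Gpnmb 51.7-fold and Apoe 25.9-fold. A second Gpnmb probe rose by log2 3.82. The genes named here were chosen after their values were seen. Log2 changes with normexp background were −5.38 (Ltf), −2.37 (Prtn3), 2.33 (Csf3r), −4.30 (Ppbp) and −0.45 (Axl).

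The shift of cell type markers was set against 4 explanations. A lower share of muscle cells alone would raise the markers of every other cell type alike. The list medians of macrophage and endothelial markers lay 6.502 apart on the log2 scale with opposite signs. The lower quartile of the former (1.74) lay above the upper quartile of the latter (−0.30). This argues against a lower share of muscle cells as the only explanation. The opposite signs are part of the pattern to be explained, so they are no independent test. Scaling of the arrays would move all lists alike. Over 5 other settings, the medians of the macrophage, adipocyte, myogenic, cell cycle, endothelial and pericyte lists kept their direction. The smallest in size was 0.968, that of endothelial markers with normexp, which corrects background and does not scale arrays. Median, spike-in and no scaling shift every gene by 1 constant. The largest such shift, with spike-in scaling, moved the pericyte median from −1.75 to −1.29. Constants of that size could not turn these medians, so their kept direction was fixed in advance. A candidate explanation is more RNA of macrophages in the Magic-F1 arrays. Of 22 macrophage genes outside the lists fixed beforehand and outside the 12 largest rises, 21 were called higher and 1 lower, with a median of 3.60. Abundant macrophage transcripts stood high in Magic-F1 and clearly above background in control cells, at 9.34 against 4.74 for Mpeg1, 8.64 against 4.80 for Ctss and 7.41 against 1.61 for Cd68. Lyz2, also made by neutrophils, stood at 8.18 against 8.48 by its brightest probe, and another of its probes was higher (log2 2.97). These abundant genes were also chosen after their values were seen. Likewise, the control arrays may hold more RNA of neutrophils and their precursors. Of 11 granule genes outside those lists and the 12 largest falls, 9 were called lower and 1 higher, with a median of −4.66. With normexp background these 9 falls were smaller, from −5.38 (Ltf) to −1.21 (Cxcr2). The labels name no sort or gate that would remove such cells. An effect of the genotype on the cells that grew out, and changes of expression within the satellite cells, were not tested and stay open.

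The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many probes were called in 1 of the 10 splits, the real one with 18590, against 0 in the highest of the others. For genes this was also 1 of 10, with 11456 against 0. As many gene lists were called in 2 of 10 splits, the real one with 11 and 1 that joined Magic-F1 replicate 1 with control replicates 1 and 2, also with 11. The other splits called 7 to 10 lists, although none of them called a gene. Each split but the real one set 2 arrays of 1 group and 1 of the other against the rest. Part of the group difference thus stayed in their contrast, where camera can still call shifted lists. The rest entered the spread between arrays, which hides changes of single genes. These counts therefore cannot decide whether the calls arise from the real grouping.

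The 2 columns of the deposited table for the arrays numbered 1 hold other values than the scanner files. On 126 bright probes spotted 10 times, the Magic-F1 column differed from its file by 0.046 log2 beyond spot noise and the control column by 0.023. A second scan of the same hybridised arrays would share the deviations of single spots. These correlated at 0.612 and 0.468 between column and file, below the highest correlation between different arrays (0.731), which argues against it. Exchanged columns are argued against as well, since each column lay farther from the other group's file than from its own by at least 1.851. Another array of the same RNA stays open as a candidate explanation. The distance to the own file was at most 0.687 of that between the closest 2 files of the group (0.067 for Magic-F1, 0.039 for control). Files of another sample lay within that distance of the columns as well, at 0.061 (Magic-F1 replicate 3) and 0.036 (control replicate 2). The remaining files of the groups lay farther, at 0.074 and 0.146. This closeness therefore does not single out the same RNA. With both arrays numbered 1 left out, 17303 probes passed. No biological explanation was tested for this pattern.

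Probes of 1 gene mostly changed alike. Among 7718 pairs of tested probes of a gene within 500 kb, the 344 pairs within 100 bp differed by a median of 0.08 log2 and those over 5000 bp apart by 0.58. In 36 pairs, from 31 genes, 1 probe changed by under 1 and the other differed by at least 4, with the larger change a fall in 29 pairs and a rise in 7. In 4 of them the probes lay within 500 bp, as for Dcun1d1 (0.24 and −9.22), Rhoq (−0.32 and −4.58), Slc38a1 (0.94 and −3.76) and Tma7 (−5.08 and −0.47). These 4 were chosen after their values were seen.

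Genes that differ between the sexes were read as well, with the labels calling the mice female. Xist, made from the inactive X chromosome, was 9.11-fold higher in Magic-F1 (−0.68 ± 0.01 against −3.86 ± 0.09, SD, n = 3 each). The Y-linked Ddx3y stood at −0.78 ± 0.01 against −0.22 ± 0.08 and Kdm5d at −3.25 ± 0.06 against −2.64 ± 0.05, both well above background on all 6 arrays. Under spike-in scaling their changes were −0.10 (adjusted p = 0.255) and −0.16 (adjusted p = 0.111), where the adjusted p over the 22 alternatives began at 8.41e-06 and 7.13e-06. The Y-linked Eif2s3y was at least 2.33-fold lower and well above background on the control arrays only. There it stood low, at −4.09 ± 0.20, where the lowest signal well above background was −5.25 to −4.80. Uty, the remaining Y-linked gene of the list, had no tested probe. With normexp background the log2 changes were 1.56 (Xist) and −0.54 (Eif2s3y). Signal of the Ddx3y and Kdm5d probes on all 6 arrays is at odds with the female label, unless these probes also bind other transcripts, which was not checked. The differences in Xist and Eif2s3y leave open that the sex of the mice differed between the groups. Such a difference was not tested and could not be told apart from that of the genotype.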
